A study of Mus musculus with 6 samples.

How the data were processed

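Small RNA was sequenced from the left ventricle of 6 mice of more than 50 weeks, 3 WT and 3 HCM mutant, grouped by the genotype in the labels. The titles call them biological replicates, and they were treated as separate animals. Per the labels' protocols, total RNA was isolated with a miRNA isolation kit and made into multiplexed miRNA libraries. The deposited values are reads per 1000000 miRNA reads (RPM) for each mature mouse miRNA, named in the older nomenclature in which an asterisk marks the minor arm; the file header only calls the columns normalised. The unit was worked out from the deposited values: each column summed to 1000000 RPM less the worth of 0 to 3 reads, and 100% of values in every library were whole multiples of the worth of 1 read, within a tolerance of 0.02 reads. The aligner, counter, miRNA database release and genome build are not given in the sources used here.

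The whole reads behind the RPM values were recovered from these steps. 1 read was worth 0.191 RPM in the deepest library and 0.403 RPM in the shallowest, so that a count of 0 allowed up to 0.574 and 1.21 RPM (3 reads). For single libraries the share of the 10 most abundant miRNAs had 95% Wilson intervals such as 74.9% to 75.0% for WT replicate 1. Such intervals and floors cover counting error only, since no molecular identifiers are described. RPM is a share of all miRNA reads, so a fall of the most abundant miRNAs raises the others. The table held 698 miRNA rows, of which 220 were at 0 in all libraries and 285 were detected below the filter; the tested rows held at least 99.9% of the reads of each library. 5 rows carried several names.

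Before the data were examined, the groups, the tests, the 16 miRNA lists, the rule for named miRNAs and most of the other settings were fixed. The lists, those named as reported up or down in cardiac hypertrophy included, were drawn up from general knowledge and not from a cited source. RPM values were tested as log2(RPM + 1) with limma 3.58.1 in R 4.3.3 (trend, not robust), two-sided, for the 193 miRNAs with a mean of at least 10 RPM over the 6 libraries, without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors of log2 differences are limma's moderated standard errors. Each measured arm of a listed miRNA, minor arms included, counted as a member of its list. Lists with at least 3 measured members were tested with camera at an inter-gene correlation of 0.01, adjusted over the 15 lists tested. The exact permutation test compared the 20 assignments of 3 against 3. The named miRNAs were, in each direction, the 6 that passed with the largest change and the 6 with the highest mean, filled to 6 by smallest p where fewer passed; up to 3 of the most abundant members of each list; and miR-208a, miR-208b, miR-499, miR-1, miR-133a and miR-21. The rule named 50 miRNAs.

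The steps were tested on simulated data: in 20 rounds, reads were drawn for the 193 miRNAs with 40 of them changed, a smaller number than usual because few miRNAs were tested. limma recovered 88.2% of 2-fold and 42.2% of 1.5-fold changes, and 8.42% of its calls were false, above the nominal 5% of the adjustment. The rounds raised as many miRNAs as they lowered and drew each miRNA independently. They lacked the excess of fold changes above 0 and the correlation between miRNAs of the real data. The share of false calls under those conditions was not measured.

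Alternatives were limma without trend, sample weights, median-of-ratios and TMM scaling, equal totals, totals without the 5 most abundant miRNAs, pseudocounts of 0.5 and 10, no filter and a mean of at least 100 RPM, other thresholds, each library left out, the replicate number as a block, and edgeR 4.0.16 quasi-likelihood on the recovered reads. After seeing the data, DESeq2 1.42.0 on the recovered reads, edgeR with the block, thinning to the smallest library and the block with an estimated correlation were added. On the recovered reads edgeR called 8 miRNAs higher and 1 lower. All pairs of libraries differed by more than the sampling noise of reads, which does not show whether they came from separate animals. Each counted as 1 replicate because the titles call them biological replicates. Of the tested miRNAs, 189 matched a precursor of GENCODE M21 (GRCm38) exactly, 160 at one locus and 29 at several; this reference was used only for positions. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.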

Results

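Small RNA libraries from the left ventricle of aged mice, all more than 50 weeks old, were compared between 3 wild-type (WT) animals and 3 animals carrying the R403Q change in Myh6, which encodes the alpha-myosin heavy chain of heart muscle. The labels describe the mutant as a mouse model of HCM, taken here as hypertrophic cardiomyopathy, a disease in which the heart muscle thickens. The comparison asks which mature microRNAs (miRNAs), the short RNAs that repress messenger RNAs, differ in level between the aged mutant and the aged WT ventricle. The WT libraries held 3647223, 3719703 and 5223636 miRNA reads, and the mutant libraries held 4267939, 4154277 and 2483486. Between 367 and 407 miRNAs were detected per library, and 193 had a mean of at least 10 reads per 1000000 miRNA reads (RPM) and were tested.

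Both groups were dominated by a few miRNAs of heart muscle. miR-1, a muscle-specific miRNA, stood at 293575 ± 35456 RPM (SD, n = 3) in WT and 239189 ± 32646 RPM (n = 3) in the mutant. miR-208a, encoded within an intron of Myh6, stood at 152484 ± 19532 RPM in WT and 159956 ± 27023 RPM in the mutant. The 10 most abundant miRNAs held 73.7% ± 2.84 (SD, n = 3) of the reads in WT and 70.4% ± 1.69 (n = 3) in the mutant. This difference did not pass a two-sided exact permutation test (p = 0.2, where 3 against 3 animals allow no p below 0.1). The first principal component held 56.0% of the variance, with the WT libraries at −5.13, 0.05 and −3.62 and the mutant libraries at 1.25, 2.70 and 4.74. WT replicate 2 lay nearest to the mutants.

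In the mutant ventricle 10 miRNAs were higher than in WT and 0 were lower (limma, Benjamini-Hochberg adjusted p under 0.05). The largest changes were in both arms of the miR-21 precursor, an miRNA abundant in cardiac fibroblasts, and in miR-214 and miR-199a-5p, which share the host transcript Dnm3os at one of their loci. miR-21 rose from 1780 ± 596 RPM (SD, n = 3) in WT to 4904 ± 1987 RPM (n = 3) in the mutant, and its minor arm miR-21* from 7.35 ± 3.56 to 27.9 ± 11.0 RPM. miR-214 rose from 457 ± 155 to 1187 ± 428 RPM and miR-199a-5p from 24.3 ± 5.28 to 55.6 ± 5.44 RPM. Every one of the 3 mutant libraries lay above all 3 WT libraries for each of these 4 miRNAs.

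On the log2(RPM + 1) scale, which understates the change of miRNAs with few reads, the difference was 1.83 ± 0.31 (SE) for miR-21*, 1.43 ± 0.26 for miR-21 and 1.37 ± 0.25 for miR-214, each with a limma adjusted p of 2.09e-04. For miR-199a-5p it was 1.18 ± 0.25 (limma adjusted p = 0.00220). miR-147 rose from 10.5 ± 3.36 to 23.6 ± 4.56 RPM, a log2 difference of 1.12 ± 0.27 (limma adjusted p = 0.00970). miR-125b-3p, an arm of the Mir125b-1 precursor, rose from 10.1 ± 2.46 to 23.5 ± 8.88 RPM, by 1.10 ± 0.28 (limma adjusted p = 0.0123). The abundant miR-125b-5p matched both this precursor and Mir125b-2, so its reads cannot be assigned to either. miR-497, of the miR-15 and miR-16 family, rose from 116 ± 29.5 to 236 ± 77.0 RPM (95% interval of the log2 difference 0.48 to 1.52, limma adjusted p = 0.0123). miR-142-3p, an miRNA of blood-derived cells, rose from 1065 ± 122 to 1728 ± 137 RPM (0.70 ± 0.20, limma adjusted p = 0.0333). The tenth, miR-34b-5p, was outside the rule for named miRNAs and was chosen after its values were seen. It rose from 9.34 ± 2.90 to 17.9 ± 2.98 RPM and passed at a limma adjusted p of 0.0499 with a difference of 0.90 ± 0.28. miR-21*, miR-199a-5p, miR-147, miR-125b-3p and miR-34b-5p had means below 100 RPM, so the setting with that filter did not test them. Among the other settings that tested them, miR-147 passed in 16 of 19, miR-142-3p in 15 of 20, miR-497 in 14 of 20, miR-125b-3p in 12 of 19 and miR-34b-5p in 7 of 19. Without HCM mutant replicate 3 the adjusted p was 0.298 for miR-142-3p, 0.264 for miR-497 and 0.213 for miR-125b-3p, and without WT replicate 3 it was 0.159 for miR-147 and 0.267 for miR-34b-5p (limma).

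**Figure D1:**
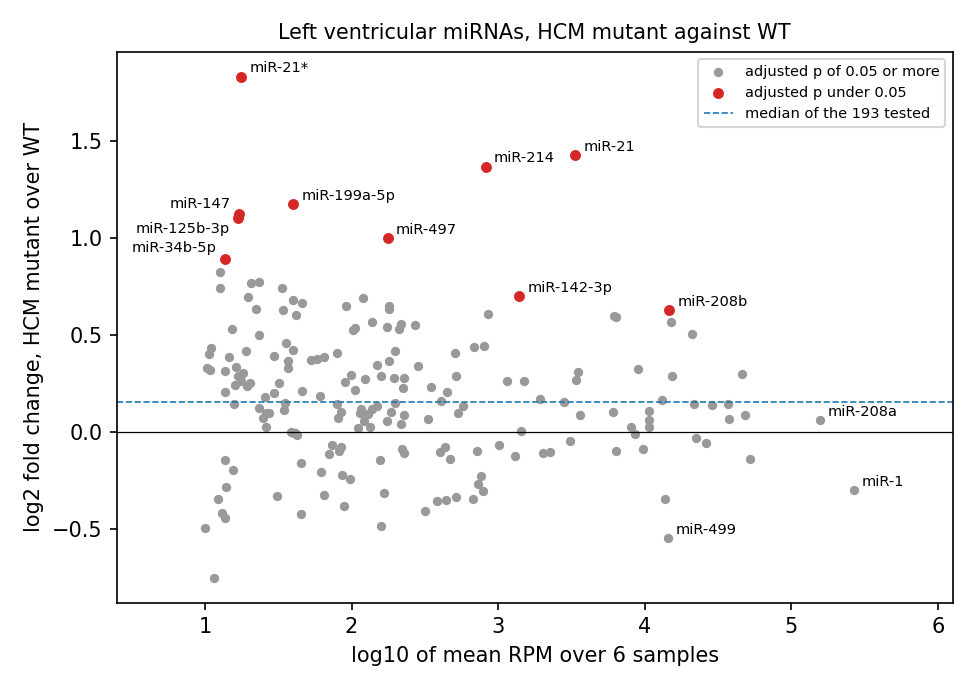
Log2 fold change of each of the 193 tested miRNAs, HCM mutant over WT, against the log10 of its mean RPM over the 6 libraries. Red points are the 10 miRNAs with an adjusted p under 0.05, all of them above 0, and the dashed line marks the median of all tested miRNAs, 0.15.

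Fold changes lay above 0 for 137 of the 193 miRNAs and below 0 for 56, with a median of 0.15. At an unadjusted p under 0.05, 38 miRNAs were higher and 4 were lower. Besides miR-499, miR-1 and miR-29c, the naming rule gave miR-874, miR-150 and miR-185 as lower, and none passed. miR-874 differed by −0.75 ± 0.27 (limma adjusted p = 0.0876), and it passed as lower with sample weights. miR-150 differed by −0.48 ± 0.26 and miR-185 by −0.41 ± 0.22 (limma adjusted p = 0.292 and 0.294). For miR-874 and miR-185 all 3 mutants lay below every WT library. The groups did not overlap for 40 miRNAs, or 20.7% of those tested, where chance gives 10%. The median depended on the scaling. It was −0.00081 after median-of-ratios scaling, which sets the median near 0 by design and called 5 miRNAs higher and 1 lower. It was 0.02 with totals that left out the 5 most abundant miRNAs, which called 6 higher and 1 lower. The number of calls also changed when single libraries were left out. Without WT replicate 3, 1 miRNA passed, miR-21*, and without WT replicate 1, 5 passed. In contrast, 22 passed without WT replicate 2 and 24 without HCM mutant replicate 1. A smaller sample also raises p, so a lost call alone does not show that a change rested on that animal. With each library left out, the log2 difference lay between 1.11 and 1.81 for miR-21 and between 1.09 and 1.63 for miR-214. It lay between 0.67 and 1.09 for miR-34b-5p and between 0.49 and 0.77 for miR-208b.

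Of the 3 miRNAs hosted by the myosin heavy chain genes, 1 passed. miR-208b, encoded in an intron of Myh7, the gene of beta-myosin heavy chain, rose from 11455 ± 389 RPM (SD, n = 3) in WT to 17919 ± 3505 RPM (n = 3) in the mutant, by 0.63 ± 0.18 on the log2 scale (limma adjusted p = 0.0282) and in 3 of 3 mutants. This call was lost under 11 of the 20 other settings in which it was tested, among them both scalings that brought the median close to 0. Its log2 difference lay between 0.46 and 0.77 in these settings. miR-499, encoded in an intron of Myh7b, stood at 16971 ± 730 RPM in WT and 11697 ± 1804 RPM in the mutant, with all 3 mutants below every WT library, and did not pass (−0.55 ± 0.17, limma adjusted p = 0.0559). It passed as lower in several settings, among them with edgeR's quasi-likelihood test on recovered reads and after median-of-ratios scaling. miR-208a did not pass (0.06 ± 0.15, limma adjusted p = 0.817; 95% interval −0.24 to 0.37). As a share of miR-208a in the same library, miR-208b was 7.73%, 8.44% and 6.60% in WT and 11.2%, 9.68% and 12.9% in the mutants. The list of these 3 miRNAs did not pass as a group (camera adjusted p = 0.671), with 1 member higher, and 1 higher and 1 lower when adjusted over the list alone.

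**Figure D2:**
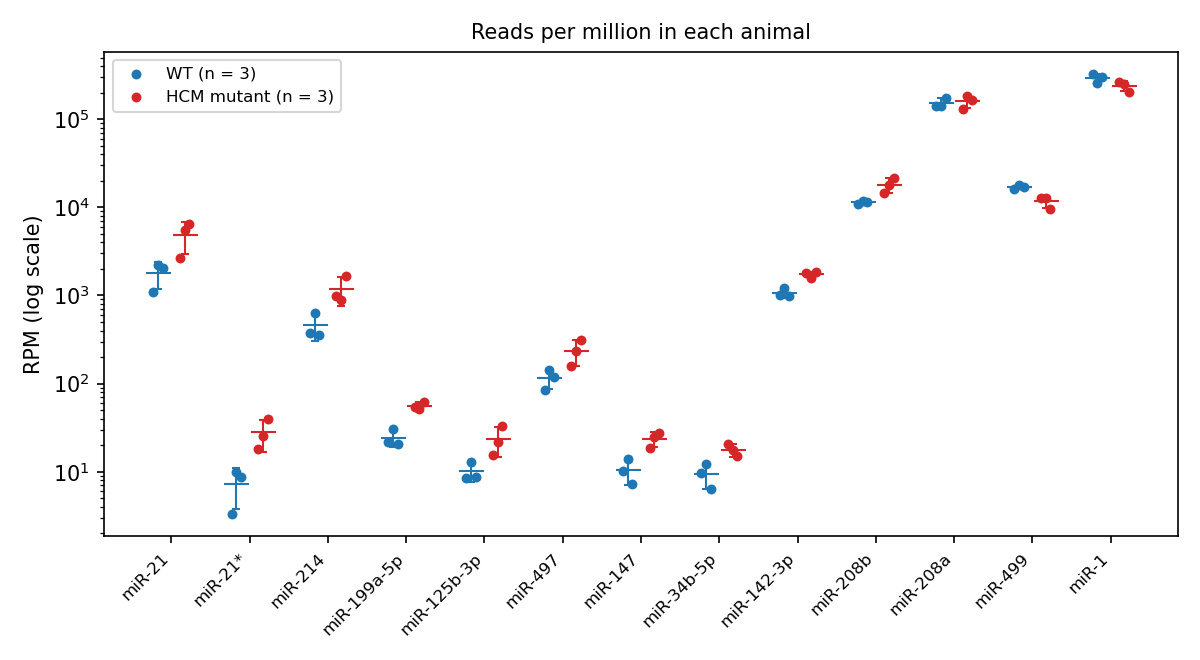
RPM on a log scale for each of the 3 WT (blue) and 3 HCM mutant (red) libraries, for the 10 miRNAs that passed and for miR-208a, miR-499 and miR-1, which did not. Points are single animals, and the dash and bar give the mean ± SD; all mutants lie above all WT libraries for miR-208b and below them for miR-499.

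Among the other miRNAs of heart and skeletal muscle, none of miR-1 (−0.30 ± 0.14, limma adjusted p = 0.209), miR-133a (−0.14 ± 0.22, limma adjusted p = 0.785) and miR-208a passed. The muscle list of 5 did not pass (median −0.14, camera adjusted p = 0.155), with 1 member higher, and 1 higher and 1 lower when adjusted over the list alone. It passed as down without WT replicate 2 (camera adjusted p = 0.0493), and its adjusted p over all libraries was 0.521 with an estimated correlation.

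By miRNA list, with lists drawn up from general knowledge, 3 of the 15 lists tested passed with camera at its preset correlation of 0.01. Of the 7 measured fibroblast-enriched and pro-fibrotic miRNAs, all had fold changes above 0, 4 were higher among all miRNAs tested and 5 when adjusted over the list alone. Their median of 1.18 lay 1.02 above the median of all tested miRNAs (camera adjusted p = 8.78e-06), and the adjusted p was 0.521 with an estimated correlation. With only the more abundant arm of each miRNA kept, the list had 5 members and a median of 0.65 (camera adjusted p = 0.00175 at the preset correlation). The members that passed were miR-21, miR-21*, miR-214 and miR-199a-5p, and miR-199a-3p passed over the list alone (141 ± 25.7 RPM in WT, 220 ± 22.9 RPM in the mutant). Of the 22 miRNAs of the list reported up in cardiac hypertrophy, 6 were higher and 8 when adjusted over the list alone, with a median of 0.46, or 0.31 above that of all tested (camera adjusted p = 6.99e-06; adjusted p = 0.521 with an estimated correlation). All 7 fibroblast-enriched members belong to this list too, so the 2 results are not independent. Of the 20 miRNAs of the list reported down in cardiac hypertrophy, 0 passed by limma, over all miRNAs or adjusted over the list alone, and 6 had fold changes above 0, with a median of −0.09, or −0.25 relative to all tested (camera adjusted p = 2.39e-04; adjusted p = 0.482 with an estimated correlation). In this list 15 members come from the miR-29 and miR-30 lists, minor arms included. With an estimated correlation, 0 of the 15 lists passed, against 3 with the preset one.

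**Figure D3:**
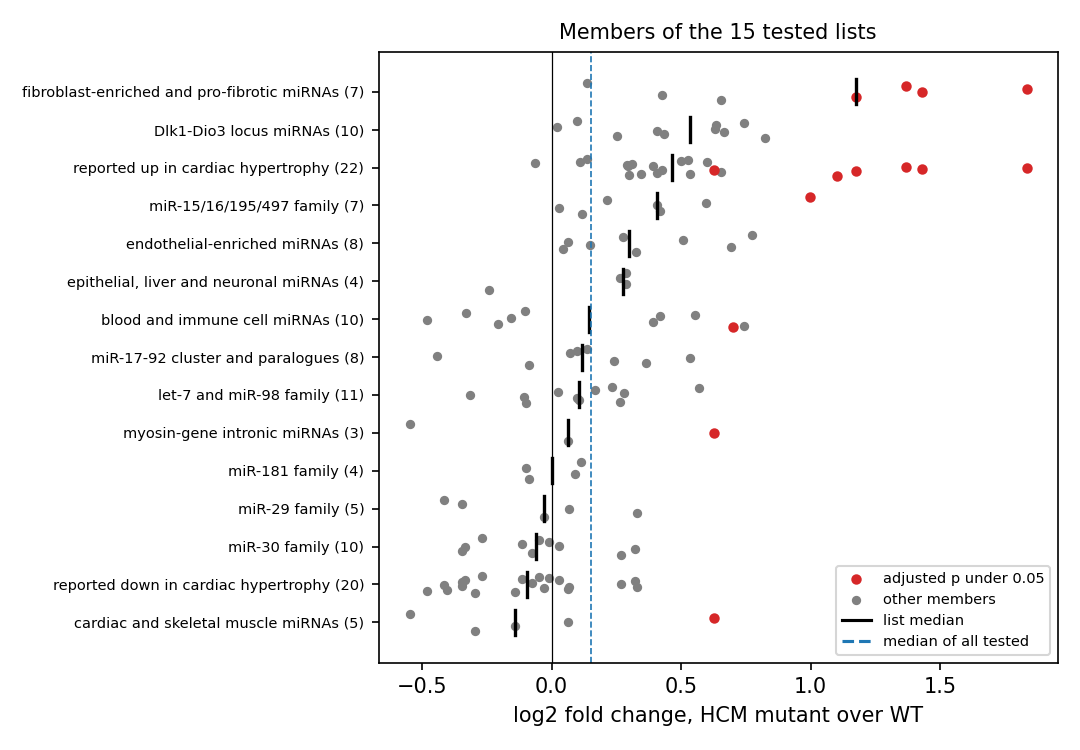
Log2 fold change, HCM mutant over WT, of each member of the 15 tested lists, with the number of measured members in brackets. Red points are miRNAs with an adjusted p under 0.05, black lines are list medians and the dashed line is the median of all tested miRNAs. The fibroblast-enriched list, with each measured arm as a member, has the highest median, 1.18.

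The remaining lists did not pass with camera. The miR-29 list of 5, minor arms included, had a median of −0.03 (adjusted p = 0.155), and 0 members passed by limma. Its most abundant members were miR-29b (36544 ± 3754 RPM in WT, 38111 ± 1072 RPM in the mutant), miR-29a (22478 ± 1657 and 22067 ± 2138 RPM) and miR-29c (15461 ± 833 and 12162 ± 754 RPM). miR-29c differed by −0.35 ± 0.17 (limma adjusted p = 0.225), with all 3 mutants below every WT library. It passed as lower with DESeq2 on recovered reads and with edgeR and the replicate block. The miR-30 list of 10, minor arms included, had a median of −0.06 (adjusted p = 0.0839). With only the more abundant arm of each miRNA kept, 5 members had a median of −0.05 (camera adjusted p = 0.165). The list of 10 passed after median-of-ratios scaling (adjusted p = 0.0455). It also passed without any one of WT replicate 1, HCM mutant replicate 2 or HCM mutant replicate 3 (adjusted p = 0.00845, 0.0291 and 0.0240). These are values at the preset correlation, and over all libraries its adjusted p was 0.750 with an estimated correlation. All 10 measured miRNAs of the imprinted Dlk1-Dio3 locus had fold changes above 0 (median 0.53, adjusted p = 0.139). Of these, 0 passed over all miRNAs and 5 when adjusted over the list alone, among them miR-411 (140 ± 42.4 RPM in WT, 219 ± 74.6 RPM in the mutant) and miR-376a (35.4 ± 6.20 and 57.1 ± 13.2 RPM).

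Lists of other cell types of the ventricle did not pass either. The 8 endothelial-enriched miRNAs all had fold changes above 0 (median 0.30, camera adjusted p = 0.204), with 0 passing over all miRNAs and 3 when adjusted over the list alone. Among these was miR-23b (17602 ± 3469 RPM in WT, 24747 ± 1408 RPM in the mutant), whereas miR-126-3p stood at 20765 ± 4627 and 22718 ± 2447 RPM. The 10 blood and immune cell miRNAs had a median of 0.14 (adjusted p = 0.824), with 1 member higher and 2 when adjusted over the list alone. miR-486 stood at 2355 ± 414 RPM in WT and 2177 ± 225 RPM in the mutant. Only 2 smooth muscle-enriched miRNAs were measured, too few for a list test, and neither passed. miR-143 differed by 0.14 ± 0.17 and miR-145 by −0.30 ± 0.22 (limma adjusted p = 0.685 and 0.441). The 4 epithelial, liver and neuronal miRNAs had a median of 0.28 (adjusted p = 0.824), with 0 passing by limma. The 7 members of the miR-15 and miR-16 family list, which holds miR-497 and the minor arm miR-322*, all had fold changes above 0 (median 0.41, adjusted p = 0.204). Of these, 1 passed, and 2 when adjusted over the list alone. The let-7 and miR-98 list of 11, minor arms included (median 0.11, adjusted p = 0.710), had 0 passing and 1, let-7i, over the list alone. The 8 members of the miR-17-92 cluster and its paralogues (median 0.12, adjusted p = 0.671) and the 4 of the miR-181 family (median 0.00215, adjusted p = 0.396) had 0 passing by limma, also over each list alone. For the blood, epithelial, let-7, miR-17-92, miR-181 and myosin lists the camera direction was down while the median and mean lay above 0. camera compares a list with the other miRNAs, whose fold changes lay above 0 for the most part.

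By own match of the mature sequences to the precursor transcripts of GENCODE M21 (mouse build GRCm38), miR-21 (TAGCTTATCAGACTGATGTTGA) lay at chromosome 11, 86584120 to 86584141, and miR-21* at 86584082 to 86584103, both on the minus strand and overlapping an exon of Vmp1. miR-214 (ACAGCAGGCACAGACAGGCAGT) lay at chromosome 1, 162223438 to 162223459, in an exon of the noncoding gene Dnm3os. The sequence of miR-199a-5p matched 2 loci, one in an exon of Dnm3os at chromosome 1, 162217844 to 162217866, and one at chromosome 9, 21496537 to 21496559. Its reads cannot be assigned to one of them. miR-208a lay at chromosome 14, 54949072 to 54949093, in an intron of Myh6, and miR-208b at chromosome 14, 54975710 to 54975731, in an intron of Myh7. miR-499 lay at chromosome 2, 155622893 to 155622913, in an intron of Myh7b, and miR-142-3p at chromosome 11, 87756903 to 87756925, in an intron of Mir142hg. miR-497 lay at chromosome 11, 70234730 to 70234751, miR-147 at chromosome 2, 122640850 to 122640871, in an exon of AA467197, and miR-125b-3p at chromosome 9, 41581980 to 41582001, in an intron of 3110039I08Rik.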

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

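All 10 called miRNAs kept their direction in each of the 20 settings in which they could be tested. For each of them every mutant library lay above every WT library. Only settings that rescaled the reads or drew them anew could therefore have changed the direction. Equal totals changed nothing because the totals were already equal. miR-21* passed in all 19 settings that tested it, miR-214 in 19 of 20, and miR-21 and miR-199a-5p in 18 each of 20 and 19. miR-147 passed in 16 of 19, miR-142-3p in 15 of 20, miR-497 in 14 of 20 and miR-125b-3p in 12 of 19. At the other end, miR-34b-5p passed in 7 of 19 and miR-208b in 9 of 20. For single named miRNAs, with equal totals counted in, 877 of the alternative values kept side and direction, 47 passed newly, 36 no longer passed and 82 changed sign without passing.

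Against 10 higher and 0 lower, an adjusted p under 0.1 gave 19 and 2 (21 in all), and an absolute log2 fold change of at least 1 gave 6. Sample weights gave 34 and 3 (37). Median-of-ratios scaling gave 5 and 1 (6), TMM scaling 4 and 0, and totals without the 5 most abundant miRNAs 6 and 1. edgeR on recovered reads gave 1 lower, no filter 2 lower (of 478 tested), a mean of at least 100 RPM 1 lower, and DESeq2, chosen after seeing the data, 4 lower. Scaling that lowers the median lowers each fold change with it; otherwise the cause was not tested. Leaving out one library gave 1 to 24 calls, 1 to 22 higher and 0 to 3 lower, with 1 without WT replicate 3, 5 without WT replicate 1, 22 without WT replicate 2 and 24 without HCM mutant replicate 1. Without WT replicate 3, miR-214 had an adjusted p of 0.0699 (range over its alternatives 1.27e-12 to 0.0699).

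Whether the replicate numbers pair the animals stays open, since the labels do not say. Same-numbered deviations correlated at 0.51, −0.07 and 0.18, and not every sample correlated best with its own number. Deviations from the mean of so few libraries depend on one another, so these correlations cannot decide the question. With the replicate block, limma called 16 higher and 1 lower (17), all 10 main calls among them, and edgeR with the block, added later, 23 and 10 (33).

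Lists were tested again under fewer settings than single miRNAs. The count of 3 stayed at 3 or 4 with median-of-ratios and TMM scaling, a pseudocount of 10, a mean of at least 100 RPM, the more abundant arm only, the replicate block and each library left out, but 0 lists passed with an estimated correlation, with fry, which does not compare a list with other miRNAs, and with the replicate block and an estimated correlation. The share of the most abundant miRNAs differed by −3.93 percentage points for 5 and −1.51 for 20. Thinning all libraries to the smallest gave 11 higher and 0 lower, so unequal depth moved the count little.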

Other observations

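The tests of explanations below, other than the splits of the samples, were chosen after the results were seen.

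Below the filter, miR-146b, a miRNA of inflammatory signalling, stood at 3.96 ± 1.52 RPM (SD, n = 3) in WT and 15.1 ± 6.33 RPM in the mutant, and it passed as higher when no filter was used. miRNAs of the miR-290 and miR-302 clusters, known from embryonic stem cells, summed to 33.5, 18.3 and 13.8 RPM in the WT libraries and 11.9, 9.63 and 10.5 RPM in the mutants, or 26 to 122 reads per library. The 3p arms of miR-465 stood at 15.9, 6.72 and 2.87 RPM in WT and at 1.17, 1.20 and 0 RPM in the mutants.

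Of the 10 splits of the 6 samples into 3 and 3, 1, the real one, gave 10 or more miRNAs, and the highest of the others gave 0. For lists the real split gave 3, 5 of the 10 splits gave as many, and the highest of the others gave 6. The splits are too few for a share under 0.05.

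More miRNAs lay above 0 than below. The summed share of the 5 most abundant miRNAs was 58.8% ± 3.34 (SD, n = 3) in WT and 54.9% ± 2.61 in the mutant (exact permutation p = 0.2); among them miR-1 and miR-22 had lower means in the mutant, and miR-208a, miR-26a and miR-125b-5p higher ones. A lower summed share under RPM scaling, with miR-1 as its main part, may account for the skew: with totals that left out these 5, the median log2 fold change was 0.0225, against 0.15. However, equal totals of the remaining miRNAs would also draw the median towards 0 if many of them had truly risen. The value therefore cannot separate an effect of scaling from a broad rise. The difference of miR-214 exceeds this shift, since it lay 1.22 above the median. No biological explanation was tested for the shift.

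miR-208b rose while miR-208a and miR-499 did not pass, with miR-499 below WT in all 3 mutants. A fixed share of miR-208a reads assigned to miR-208b would leave their ratio level, whereas the within-library log2 ratio was 0.57 higher in the mutants, without overlap. One scaling factor per library cancels in the ratio of miR-208b to miR-499, which was 1.18 higher, also without overlap. Both ratios combine the same differences that prompted the tests, so they count only against these explanations as the whole cause and give no independent evidence of the pattern. A link to the myosin genotype stays open as a hypothesis: the exact permutation p of the ratio of miR-208b to miR-499 was 0.1, the smallest 3 against 3 animals allow, and no other group separates genotype from other differences between the animals.

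4 of the 7 fibroblast-enriched miRNAs and miR-142-3p passed as higher, and the camera call of the fibroblast-enriched list was lost with an estimated correlation (adjusted p = 0.521). fry asks another question, whether the list moves one way without comparing it with other miRNAs, and did not pass either (adjusted p = 0.132). A lower share of heart muscle cells would raise the markers of other cell types alike only if heart muscle cells lacked them. The lists do not ensure this, and it was not tested. The mean of the 7 fibroblast-enriched miRNAs less that of the endothelial and smooth muscle ones was 0.74 (log2) higher in the mutants. The groups did not overlap (exact permutation p = 0.1, the smallest possible). This difference is built from the changes that prompted the test, and its reading depends on that condition. It cannot tell whether a lower muscle share was part or all of the cause, which stays open. More blood left in the tissue would raise miR-451, miR-144 and miR-486, taken as miRNAs of red blood cells, with miR-142-3p. However, miR-142-3p less their mean was 0.92 higher, without overlap (exact permutation p = 0.1). This value also holds a change already seen, and it counts only against more blood as the whole cause. More fibroblasts, more immune cells or a change within these or other cells, heart muscle cells included, may each remain. RNA of the left ventricle does not assign these miRNAs to a cell type, and these values do not separate the possibilities.

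A further hypothesis was that miRNAs from one precursor or one genomic cluster change together. The first test used 21 precursors with both arms measured and each arm matched to 1 locus only, which are not independent replicates. The fold changes of the arms correlated with r = 0.81 (one-sided permutation p = 5e-05) and rho = 0.73 (permutation p = 0.00018). Without miR-142-3p and miR-21, the 2 farthest from the median, r was 0.59 (permutation p = 0.0039). In 39 pairs of precursors within 10 kb on one strand, fold changes differed by 0.28 on average against 0.40 for random pairs (permutation p = 0.0092). The 2 tests form one family, and both left out miRNAs that matched several loci, such as miR-125b-5p and both arms of miR-199a. Both results are consistent with joint transcription, found and tested on the same data.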
